A study of Mytilus galloprovincialis and Mytilus trossulus with 84 samples.

How the data were processed

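Gill tissue of Mytilus galloprovincialis and Mytilus trossulus was profiled on two-colour oligonucleotide arrays, 1 animal per array. Per the labels, the mussels were acclimated for 4 weeks at 13 °C, the water of the heated animals was warmed by 6 °C per h from 13 to 32 °C, and animals were moved to a separate tank at 24, 28 and 32 °C and held there for 1 h before dissection. Controls stayed at 13 °C and were sampled at the start and at each of those points. This gave 14 groups of 6 animals, 84 arrays in all. The sample carried Alexa Fluor 647 and a reference pool of the same species Alexa Fluor 555, with no dye swap, so a dye effect of a probe is shared by all arrays of a species and drops out of a comparison within it. The label of the pool names more kinds of sample than the number of samples it gives, so its make-up is not settled.

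Most probes were designed from Mytilus californianus, and 556 probes from M. galloprovincialis. Each array held 105072 features, of which 1325 were control spots and 103747 were spots of 44570 probes for 11512 sequences. Gene names are the descriptions in the scanner files; 6875 sequences had no significant hit, 52 files gave some descriptions as unknown, and for 1104 features the description differed between files. The sequence identifiers match no entry of the reference gene table, so no coordinates were used.

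The deposited values were of 3 kinds. The scanner files hold raw mean signals of both channels in intensity units, per the file headers as read by Agilent Feature Extraction from GenePix scans, with the local background medians beside them and not subtracted. The deposited scanner files also hold a log10 ratio of red over green, which Feature Extraction made after background correction, spatial detrending and dye normalization. The headers give version 9.5.1.1 for the 12 start controls and 9.5.3.1 for the other 72 arrays. The authors' value table holds log2 ratios of sample over reference, which from their values were taken relative to the median of the control arrays of the same species and ramp point; the table states neither its scale nor its centring.

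The mean signals were background-corrected with normexp (offset 50) and normalized within arrays by loess with the control spots given no weight (limma 3.58.1, R 4.3.3). Spots marked as outliers were removed and the spots of a probe averaged. A probe was kept when, in each species, red was well above background on at least 6 arrays and green on at least 50% of arrays, with 3 or more unmarked values per group. This kept 10327 probes for 5156 sequences, 2941 with a description and 1943 with an informative one, and 0.093% of values were missing. Of several probes of a sequence, the one with the highest mean signal was used; 208 sequences were read by an M. galloprovincialis probe and 2878 had more than 1 kept probe.

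Sample signal was well above background on 11 to 44.6% of the spots of an array, with a median of 22.6%, and reference signal on a median of 36.2%. In the 6 heat comparisons on simulated data with the same groups, limma found 47.2 to 64.7% of changes of 1 log2. It found 81 to 100% of changes of 2 log2. Of species differences it found 19.1 to 28.1% at 1 log2 and 71.1 to 80.6% at 2 log2. At most 3 of 4956 unchanged sequences were called falsely. The simulated noise was independent between sequences and arrays, without scan-day effects, so it does not give the false calls of the real arrays.

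Main values use 82 arrays. The scanner files of M. trossulus replicate 4 of the 32 °C control and heated groups each match the column of the other in the authors' value table, so both were left out. This departs from the plan made before the data were examined, which used all 84; counts with both arrays as labelled and with their labels exchanged are given beside the value or in the last part. For M. trossulus at 32 °C they were 30 and 437, against 265.

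A linear model with 1 mean per group was fitted to each sequence with empirical Bayes variances (residual df 68, prior df 3.3). The shared effect of temperature was an F test of 24, 28 and 32 °C against all 13 °C controls of the same species, averaged over species, and the interaction an F test of the species difference in those terms. As in the two-way design of the authors, a sequence with an interaction was not counted as a shared effect and the species term was not read. Each heated group was also compared with the control of the same ramp point, these differences between species and between 24 and 32 °C, and the controls over time by an F test. Adjusted p is Benjamini-Hochberg over the 5156 sequences of a comparison, with calls under 0.01. Values after ± are SE unless given as SD. A fold against controls of which none was well above background is a lower bound, the lower of that of the sample channel against the background floor and that of the ratio. Saturated spots were kept at their value, so a rise read on them is a lower bound; CCAAT/enhancer binding protein and c-Jun were saturated on 1 heated array in some groups.

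Gene lists were written as name patterns before the data were examined, 24 for pathways and 8 for markers of tissues. Of these 32, 29 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, with calls under 0.01. In all 32 of 319 pairs of list and comparison passed, and 13 of them passed with an estimated correlation. Counts of called members are given with the adjustment over all sequences; fry was run as a further alternative.

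Named genes were chosen by a rule fixed before the data were examined, among called sequences with an informative description and 1 per description, that with the smallest p: for the shared effect the 10 largest rises and falls at 32 °C, for the interaction the 12 smallest p, for each heat comparison the 5 largest rises and falls, for each species difference, change from 24 to 32 °C and time course the 5 smallest p, and up to 4 members of each list by smallest p. Further list members were named after their values were seen.

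The alternatives were no background correction, Agilent's own log ratios, median centring, between-array quantile scaling of the mean signal, the authors' value table, no filter and a strict filter (90% of arrays) on dim probes, every probe, the mean of probes, M. californianus probes alone, scan day or replicate number as a block, array weights, a threshold of 0.05, an ordinary F test and other sets of controls. Leaving out each array, scan day as a random block, both treatments of the 2 exchanged arrays, leaving out controls with raised chaperones and the direction, on a scan day, of sequences called without it were added after seeing the data. Relabelled values of the last are means over all divisions of the arrays of that day, the real one included. With equal numbers of heated and control arrays they are 50% by construction, so they give no chance level. The slide could not be used as a block, since the files do not give it. Replicate numbers were not used to pair the animals. Arrays of the same number had mean correlations of 0.01 to 0.12 between groups, against -0.02 to 0 for other numbers. Arrays of the same scan day had 0.02 to 0.11, against -0.04 to -0.01 for other days. A weak structure by number and day is thus present, which the main fit leaves out and the blocks take up. Each count was set against 100 splits of the same arrays into groups of the same sizes. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures, and statmod 1.5.0 was used for the random blocks.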

Results

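Gill RNA was measured in 2 blue mussels of the Pacific coast, the invasive Mytilus galloprovincialis and the native Mytilus trossulus, warmed as on a hot day at low tide. Each of the 84 arrays held the RNA of 1 animal. In each species, 6 animals were sampled at the start of the ramp, 6 heated animals after 1 h at 24, 28 and 32 °C, and 6 controls kept at 13 °C beside each heated group, which made 7 groups of 6 per species. Every value is a log2 ratio of the sample over a pool of RNA from the same species, so a level was compared within a species and not between species. The probes came mostly from another mussel, Mytilus californianus. On a single array between 11 and 44.6% of the spots were well above background in the sample channel, with a median of 22.6%, and 5156 sequences were tested. Of the 5156 sequences, 1943 carried an informative gene description, and those descriptions are used below as the files give them.

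The first question was which transcripts changed with temperature in both species, and the genes with the largest changes were molecular chaperones. The sequence MYC02822, described as heat shock protein 70, the chaperone that binds unfolded proteins, was higher than at 13 °C by at least 7.79 ± 0.32 at 24 °C, 8.92 ± 0.34 at 28 °C and 8.71 ± 0.37 at 32 °C (log2, mean of both species ± SE, adjusted p = 1.1e-41). These are lower bounds, since its spots were saturated on heated arrays of both species at 28 and 32 °C, and in the reference channel on controls of M. galloprovincialis. Its DnaJ partner Dnajb4 (MYC00444) rose by 4.65 ± 0.31 at 32 °C, and the small 22kd heat shock protein (MYC13322) by 3.93 ± 0.37. Dnajb4 was not well above background on part of the controls, so its rise may be larger. The 78 kDa glucose-regulated protein (MYC12947), the HSP70 of the endoplasmic reticulum, was higher by 2.96 ± 0.26 at 24 °C, 3.1 ± 0.26 at 28 °C and 1.85 ± 0.27 at 32 °C. Other large rises at 32 °C were those of a protein similar to immediate early response 5-like (MYC07287, 3.23 ± 0.22), a kelch and BTB domain protein (MYC04380, 2.73 ± 0.27), the inhibitors of apoptosis diap1 (MYC01276, 2.75 ± 0.38) and IAP-3 (MYC07382, 2.15 ± 0.3), and the transcription factor CCAAT/enhancer binding protein (MYC06119, 2.43 ± 0.21). A further 70kDa heat shock protein (MYC11933) rose by 2.79 ± 0.29 and a sequence described as STARP antigen (MYC03272) by 2.71 ± 0.35. STARP antigen was not well above background in any M. trossulus control at the 24 or 28 °C point, so its rise may be larger.

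The falls were smaller. At 32 °C the largest among sequences with an informative description were those of HSPA12B (MYC08138), a distant member of the HSP70 family, at -1.08 ± 0.22, of tektin 3 (MYC08099), a structural protein of cilia, at -1.04 ± 0.17, of a zinc finger protein (MYC00869) at -1.03 ± 0.18 and of a probable cytochrome P450 49a1 (MYC02051) at -1.03 ± 0.21. An alpha-glucosidase-like protein (MYC01260), methionine adenosyltransferase I alpha (MYC09381), a peptidylprolyl isomerase with WD repeats (MYC06806), a potassium channel (MYC00516) and galactosylceramide sulfotransferase (MYC00672) lay between -0.97 and -0.84. A sequence similar to flamingo 1 (MYC09946) was at 0.02 ± 0.17 at 24 °C and at -0.86 ± 0.18 at 32 °C.

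In all, 642 of the 5156 sequences were counted as having a shared temperature effect, of which 308 were higher and 334 lower at 32 °C. They passed a moderated F test of the species mean over 24, 28 and 32 °C against all 13 °C controls (Benjamini-Hochberg adjusted p under 0.01), with no interaction called. On simulated data the interaction test found 2.6, 42.2 and 81.4% of changes of 0.5, 1 and 2 log2 placed in M. trossulus at 32 °C alone. Differences present at several temperatures were not simulated, so their share found is not known. Some of the 642 may therefore differ between the species. Which direction had the majority depended on the processing: there were 407 higher and 292 lower with median centring, 380 and 320 with the mean of probes, 426 and 380 against the time-matched controls alone, but 286 and 354 with Agilent's own log ratios. An unadjusted p under 0.05 was reached by 1863 sequences. With scan day as a block the count was 575, and with the replicate number as a block it was 700. It was 1970 in the authors' value table, in which the controls of every time point are centred apart.

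The gene lists, fixed before the data were examined, showed which families moved together over both species. Chaperonins, the barrel complexes that fold cytosolic and mitochondrial proteins, rose in 9 of 11 measured members, with chaperonin MYC00474 at 1.93 ± 0.17, 2.04 ± 0.17 and 1.66 ± 0.17 at 24, 28 and 32 °C and T-complex protein 1 subunit beta (MYC04714) at 2.06 ± 0.22, 1.89 ± 0.22 and 1.65 ± 0.22. All 4 members of the HSP90 list rose, stress-induced-phosphoprotein 1 (MYC00279) by 1.6 ± 0.18 at 24 °C and heat shock protein 90 (MYC00166) by 1.26 ± 0.27, on a probe that was saturated in either channel on some heated and control arrays. In the HSP70 and HSP110 list 8 of 23 members rose, 1 fell and 14 did not pass, and the median of the list at 32 °C was 0.02. One of its rising members, the Hsp70-interacting protein (MYC01761, 1.26 ± 0.21 at 32 °C), is a partner and not a member of the family. Of 6 DnaJ proteins 3 rose. Of the 5 members of the endoplasmic reticulum list, 1 was called and higher at 32 °C, 3 were called and lower there and 1 did not pass. The glucose-regulated protein rose, calreticulin (MYC04943) was at 0.67 ± 0.15, 0.81 ± 0.15 and -0.03 ± 0.16 at the 3 temperatures, and the YTH domain protein 2 (MYC06312), which is no endoplasmic reticulum protein, fell to -0.62 ± 0.13 at 28 °C, and a Grp94 neighboring nucleotidase (MYC12449) was at -0.09 at 32 °C. Adjusted over the list alone, the counts were the same in these lists except for 3 members lower in the HSP70 list.

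Among stress-responsive transcription factors, 5 of 12 rose and 7 did not pass. They were CCAAT/enhancer binding protein, c-Jun (MYC06621, 1.41 ± 0.19, 1.79 ± 0.19 and 1.87 ± 0.2), both sequences described as Rel 1 (MYC10907 at 1.09 ± 0.18 and MYC08165 at 0.77 at 32 °C), and HSF (MYC03841), the factor that drives heat shock genes, at 0.55 ± 0.1 at 28 °C. In the apoptosis list, 5 of 31 members were higher at 32 °C and 3 lower. The higher ones included 3 inhibitors of apoptosis, Bcl-2 (MYC13541, 0.55) and a tumor necrosis factor receptor superfamily member 19 (MYC02394, 1.02 ± 0.24), and the lower ones programmed cell death 4a (MYC00853, -0.49 ± 0.14) and a caspase (MYC00197, -0.33). In carbohydrate metabolism, 4 of 15 members rose: 2 hexokinases (MYC07422 by 2.23 and MYC09302 by 1.57 ± 0.23 at 32 °C), phosphoenolpyruvate carboxykinase (MYC11465, 2 ± 0.24 at 28 °C) and D-lactate dehydrogenase (MYC08338, 1.06 ± 0.27 at 32 °C). Fructose-bisphosphate aldolase (MYC13332) was at -0.59 ± 0.17 and did not pass (adjusted p = 0.0101). Of 36 ion transport and solute carriers, 5 fell and none rose, among them 2 potassium channels (MYC00516 and MYC11527, the latter at -0.71 ± 0.17). In innate immune recognition, toll-like receptor 2 (MYC11376, -1.42 ± 0.19 at 24 °C) and toll-like receptor 10 (MYC05193) fell and the complement component 1 Q-binding protein (MYC02037, 0.54 ± 0.17 at 32 °C) rose, out of 36 members.

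The other lists held few called members. Of 25 antioxidant proteins 2 rose, glutathione peroxidase (MYC05766, 0.58 ± 0.13 at 24 °C) and a thioredoxin domain protein (MYC00085, 1.26 ± 0.16 at 32 °C). None of 5 NADPH-producing enzymes and none of 6 enzymes of the tricarboxylic acid cycle passed the limma test, and glucose-6-phosphate 1-dehydrogenase (MYC00045) was at -0.3 ± 0.1 at 32 °C (adjusted p = 0.0163). Of 18 translation factors, 2 rose, elongation factor 2 (MYC05455, 1.63 ± 0.33 at 24 °C) and the kinase of initiation factor 2-alpha (MYC03045, 0.97 ± 0.18). The list of cytosolic ribosomal proteins, with 1 of 13 higher, held mitochondrial ribosomal proteins among its named members, as the called one was (MYC01921, 0.54 ± 0.08 at 32 °C). Of 17 proteasome subunits 1 fell (MYC09029, -0.55 ± 0.13), and of 23 ubiquitin-conjugation proteins 2 were higher and 3 lower at 32 °C. Called members numbered 2 of 16 in electron transport, 2 of 19 among actin-binding proteins, 4 of 36 among tubulin, dynein and cilia, 4 of 24 in DNA damage and cell cycle, 4 of 33 among small GTPases and 3 of 12 among kinases.

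Markers of other tissues that a gill dissection can hold were read on the same arrays. None of 2 hemocyte, 10 gonad, 1 foot, 3 mantle, 14 digestive gland and 5 mitochondrial genome sequences had a shared temperature effect. Of 11 muscle sequences 1 rose, myosin light chain kinase (MYC09425, 1.05 ± 0.17 at 32 °C), which is found in non-muscle cells too. Of 24 ciliated epithelium sequences 2 fell, both tektin 3 (MYC08099 and MYC00230, the latter at -0.66 ± 0.14). The mitochondrial list also held cytochrome b-245 and a nuclear succinate dehydrogenase subunit, and 1 of its members passed for the interaction when adjusted over the list alone.

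**Figure D1:**
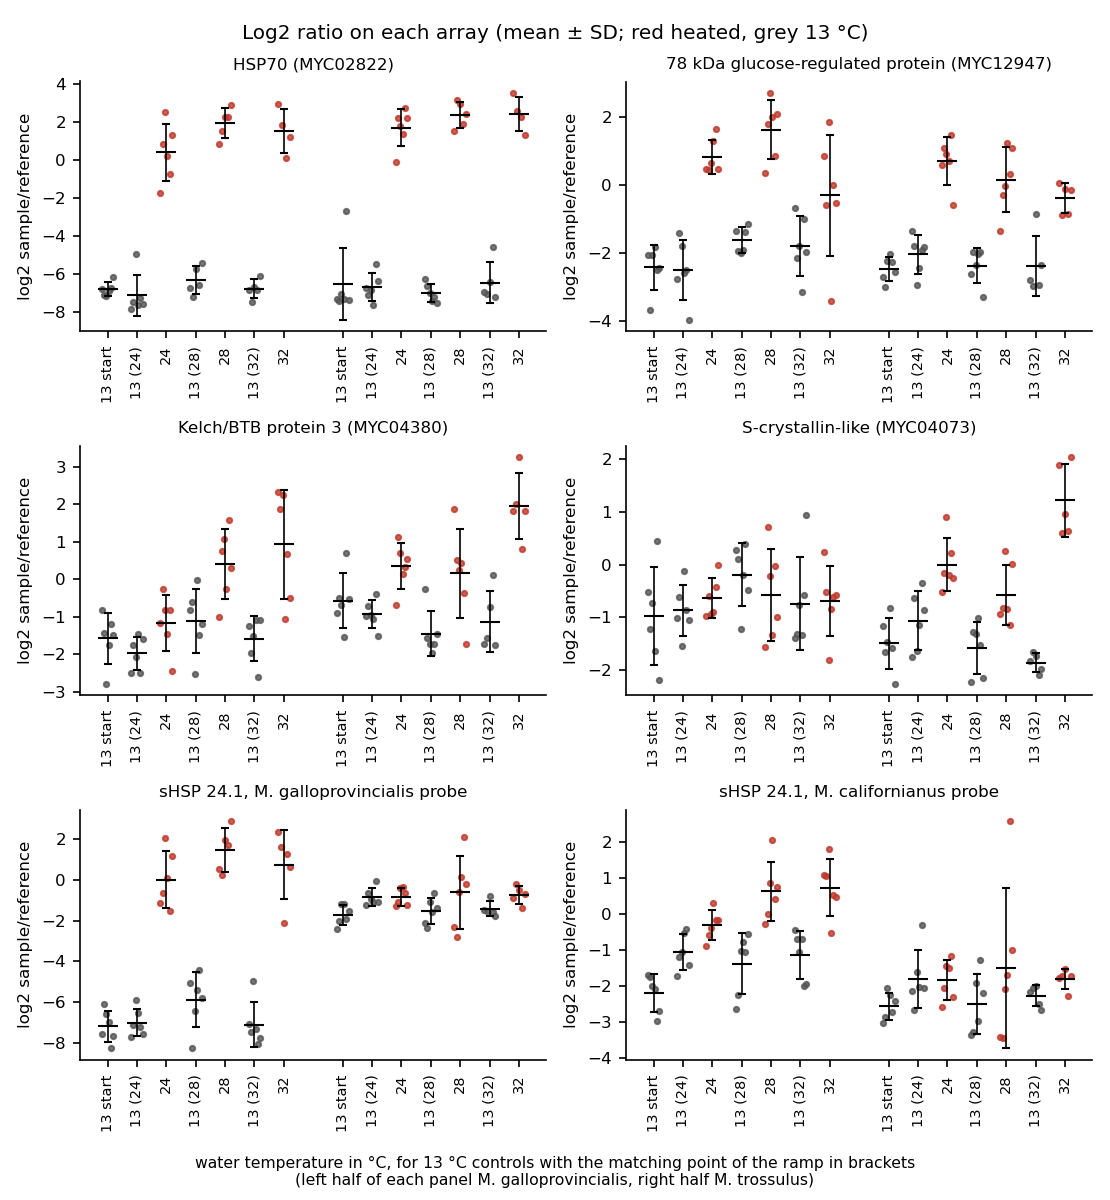
Each panel plots the log2 ratio of sample over reference (y axis) of 1 probe on every array (points, red heated and grey 13 °C) with the group mean and SD (bars), for M. galloprovincialis on the left and M. trossulus on the right. The 28 °C means of HSP70 MYC02822, saturated on 5 of 6 heated arrays in each species, were 1.96 and 2.38 against -6.35 and -7.03 in the matched controls, while the small heat shock protein MYC06670 had a mean of 1.45 against -5.89 in M. galloprovincialis and of -0.62 against -1.53 in M. trossulus on the M. galloprovincialis probe.

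In M. galloprovincialis at 24 °C, chaperones led the rises against the controls sampled at the same point of the ramp. HSP70 MYC02822 was at least 185-fold higher, with its reference saturated on 1 control (log2 7.53 ± 0.58 SE, 0.39 ± 1.51 SD against -7.14 ± 1.1, n = 6 and 6, adjusted p = 4.6e-16) and was higher in 6 of 6 heated animals than in any control. A small heat shock protein (MYC06670), read by an M. galloprovincialis probe, was higher by 7.01 ± 0.58, Dnajb4 by 4.12 ± 0.51, a scavenger receptor cysteine-rich protein (MYC01328), of a family of pathogen receptors, by 3.7 ± 0.4, and the 78 kDa glucose-regulated protein by 3.34 ± 0.47. Dnajb4 was well above background on 1 of 6 controls and the scavenger receptor on 3, so these rises may be larger. The largest falls among sequences with an informative description were those of Hairy G protein (MYC05812, -1.84 ± 0.36), betaine homocysteine methyl transferase (MYC07504, -1.67 ± 0.36), toll-like receptor 2 (MYC06213, -1.57 ± 0.18), a potassium channel (MYC00516, -1.55 ± 0.27) and poly [ADP-ribose] polymerase 14 (MYC12745, -1.44 ± 0.34). The lists of chaperonins (mean 0.87 in 11 members), HSP70 (0.94 in 23), DnaJ (1.01 in 6), HSP90 (0.83 in 4) and stress-responsive transcription factors (0.55 in 12) were higher than other genes (camera adjusted p between 1.84e-06 and 0.00406). With an estimated correlation the adjusted p was 0.00776 for HSP70, 0.00235 for DnaJ, 0.0311 for the chaperonins, 0.0452 for HSP90 and 0.0652 for the transcription factors. In all 134 sequences passed, 92 higher and 42 lower. A block for scan day gave 183 and a block for the replicate number 148, and within 4 scan days the chaperonin means lay between 0.67 and 1.06. Of the sequences called without a scan day, 93.2 to 97.3% had the same direction on that day. Relabelled arrays give 50% here by construction, and relabelled values are no chance level here or below.

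At 28 °C in M. galloprovincialis, HSP70 MYC02822 was higher by at least 8.31 (SE 0.63, n = 5 and 5, adjusted p = 2.15e-16), a lower bound since it was saturated on 5 of 6 heated arrays and its reference on 3 controls. The small heat shock protein MYC06670, saturated on 3 heated arrays, was higher by at least 7.35 (SE 0.61), Dnajb4 by 5.14 ± 0.51, STARP antigen by 4.49 ± 0.62 and the 70kDa heat shock protein MYC11933 by 3.88 ± 0.5. STARP antigen was well above background on 1 of 6 controls, so its rise may be larger. Both sequences of the 60 kDa Ro autoantigen, a protein that binds small and misfolded RNAs, were lower (MYC02058, -1.97 ± 0.41, and MYC05501, -1.36 ± 0.3), as were calpain 2 (MYC00709, -1.33 ± 0.31), solute carrier family 25 member 38 (MYC03413, -1.32 ± 0.31) and stearoyl-CoA desaturase (MYC09741, -1.27 ± 0.33), an enzyme that makes unsaturated fatty acids. For MYC02058, 1 of 2 other probes had the opposite sign. The chaperonin list had a mean of 1.07 (camera adjusted p = 4.86e-10, adjusted p = 0.00444 with an estimated correlation) and the HSP70 list a mean of 1.12 with a median of -0.13 (2.09e-05, and adjusted p = 0.00159 with an estimated correlation). The HSP90 list (mean 0.94) and the transcription factors (0.49) passed as well, at adjusted p = 0.0476 and 0.0977 with an estimated correlation. In all 151 sequences passed, 89 higher and 62 lower. There were 146 with scan day as a block and 167 with the replicate number as a block. Of those called without 1 of 3 scan days, 84.8 to 93.5% had the same direction on that day (relabelled 42.6 to 50%). This division into higher and lower rests on the loess normalization: with each array centred on its median instead, 294 passed, 58 higher and 236 lower, and the median of all sequences lay at -0.26.

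At 32 °C in M. galloprovincialis, HSP70 MYC02822, saturated on 5 of 6 heated arrays, was higher by at least 8.32 (adjusted p = 1.58e-15). The small heat shock protein MYC06670 was higher by 7.85 ± 0.61 (n = 5 and 6, adjusted p = 1.76e-16, without the 1 heated array on which it was saturated), HSP70 MYC12419 by 7.05 ± 0.57, the small 22kd heat shock protein by 4.51 ± 0.58, Dnajb4 by 4.3 ± 0.51 and hexokinase (MYC07422), the first enzyme of glycolysis, by 2.89 ± 0.44. MYC12419 and Dnajb4 were well above background on 2 of 6 controls, MYC06670 on 3 and hexokinase on 4. These 4 rises may be larger. Only 2 different informative descriptions were found among the lower sequences that passed, USoxB protein (MYC01415, -1.1 ± 0.21) and mucin 4 (MYC07559, -0.77 ± 0.19). The chaperonin list had a mean of 0.9 (5.66e-07, adjusted p = 0.0219 with an estimated correlation), the HSP70 list of 1.03 (0.000241, adjusted p = 0.00517 with an estimated correlation) and the transcription factors of 0.74, all 12 of them above 0 (2.4e-06, adjusted p = 0.00517 with an estimated correlation). The glycolysis and gluconeogenesis list had a mean of 0.51, with 1 of 15 members called (0.00886, adjusted p = 0.0876 with an estimated correlation, 0.0178 with scan day as a block). In all 74 sequences passed, 58 higher and 16 lower. The count was 112 with scan day as a block, 88 with the replicate number as a block, 47 with median centring and 46 without heated replicate 3. Within 5 scan days the chaperonin mean ranged from 0.13 to 1.62, and of the sequences called without a scan day 73.9 to 100% had the same direction on it (relabelled 45 to 50%).

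M. trossulus at 24 °C showed rises of the same families. HSP70 MYC02822 was 339-fold higher (log2 8.4 ± 0.58, 1.7 ± 0.99 SD against -6.71 ± 0.73, n = 6 and 6, adjusted p = 2.27e-18). STARP antigen was at least 15.8-fold and Dnajb4 at least 11.1-fold higher, lower bounds since neither was well above background in any control. The 70kDa heat shock protein MYC11933 was higher by 3.49 ± 0.5 and the 78 kDa glucose-regulated protein by 2.74 ± 0.47. MYC11933 was well above background on 1 of 6 controls, so its rise may be larger. HSPA12B (-1.58 ± 0.33), USoxB protein (-1.32 ± 0.21), toll-like receptor 2 (MYC11376, -1.27 ± 0.32), the tubulin TUBB2C (MYC04977, -1.03 ± 0.25) and FAM124A (MYC04153, -1 ± 0.25) were lower, and TUBB2C, whose probe used here was saturated on 1 heated array, was at -0.02 with median centring. Chaperonins (mean 1.15, camera adjusted p = 3.66e-13), HSP70 (0.9, 5.68e-05), HSP90 (1.04, 5.68e-05) and DnaJ (0.72, 0.00494) passed with an estimated correlation too (adjusted p between 0.0013 and 0.00969), and the transcription factors (0.44, 0.00494) were at adjusted p = 0.113 with an estimated correlation. Over both species the list medians at 24 °C were 0.07 for HSP70 and 0.28 for DnaJ, under these means. The 3 mantle and shell markers had a mean of 1.02 (0.5 to 1.84) on the heated arrays against 0.08 (-0.39 to 0.39) on the controls, with none called and a camera adjusted p of 0.0955; in M. galloprovincialis at 24 °C the means were 0.03 and -0.01. In all 103 sequences passed, 85 higher and 18 lower. The count was 114 with scan day as a block, 104 with the replicate number as a block and 246 with array weights, and of the sequences called without 1 of 4 scan days 84.4 to 100% had the same direction on it (relabelled 50%).

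At 28 °C in M. trossulus, HSP70 MYC02822 was higher by at least 9.41 (SE 0.6, n = 5 and 6, adjusted p = 8.27e-20), a lower bound since it was saturated on 5 of 6 heated arrays, and STARP antigen was at least 29.9-fold higher. The small 22kd heat shock protein rose by 4.66 ± 0.58, Dnajb4 by 4.43 ± 0.51 and the immediate early response 5-like sequence by 3.76 ± 0.37. Solute carrier family 25 member 38 (-1.64 ± 0.31), the splicing factor Transformer-2a (MYC11265, -0.9 ± 0.22), a phosphoinositide-interacting WD repeat protein (MYC11123, -0.88 ± 0.21) and deoxyhypusine synthase (MYC03319, -0.53 ± 0.12) were lower. Deoxyhypusine synthase was well above background on 1 of 6 heated arrays and 5 of 6 controls, so the size of its fall is uncertain. The lists of chaperonins (mean 0.96, 6.87e-09), HSP70 (1.08, 5.29e-07) and HSP90 (1.09, 4.76e-05) passed, also with an estimated correlation (adjusted p between 0.000167 and 0.00618). Over both species the median of the HSP70 list at 28 °C was 0.01. Among lists past the camera threshold in a heat comparison, ion transport was the only one that was lower (mean -0.27, 8 of 36 members above 0, camera adjusted p = 0.0041, adjusted p = 0.0649 with an estimated correlation, 0.00394 with scan day as a block). The matched control had a mean of 0.22 against -0.13 to -0.03 in the other control groups of the species, and the heated mean of -0.05 lay among those. The other control groups were scanned on other days, so a raised control and a shift between scan days cannot be told apart. In all 65 sequences passed, 54 higher and 11 lower, with 82 when scan day was a block and 68 when the replicate number was. Of those called without 1 of 3 scan days, 95 to 97.1% had the same direction on it (relabelled 50 to 51.4%).

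At 32 °C in M. trossulus, HSP70 MYC02822, saturated on 3 of 5 heated arrays, was higher by at least 8.88 (SE 0.67, n = 4 and 5, adjusted p = 2.23e-16), the small 22kd heat shock protein by 4.95 ± 0.63, Dnajb4 by 4.58 ± 0.56, the immediate early response 5-like sequence by 3.86 ± 0.41 and the kelch and BTB domain protein by 3.08 ± 0.51. Lower sequences were a selenocysteine lyase (MYC10584, -1.45 ± 0.4), AprG (MYC07009, -1.36 ± 0.36), the alpha-glucosidase-like protein (-1.31 ± 0.35), the protease furin (MYC04669, -1.12 ± 0.25, with its other probe of opposite sign) and a glucose transport protein (MYC00096, -1.12 ± 0.28). Chaperonins had a mean of 1.28 with 7 of 11 called (2e-07), HSP70 a mean of 1.15 with a median of -0.06 (0.000274), HSP90 of 1.16 (0.00318) and the transcription factors of 0.84 with 5 of 12 called (4.32e-05). With an estimated correlation their adjusted p was 0.0162, 0.0111, 0.031 and 0.0162. The protein-degradation lists were higher in this comparison, proteasome subunits with a mean of 0.51 and 2 of 17 called (0.000605) and ubiquitin conjugation with a mean of 0.31 and none of 23 called (0.00401). Their adjusted p was 0.151 and 0.0926 with an estimated correlation, and the proteasome mean within 4 scan days ranged from -0.2 to 0.95. In both lists the matched control was the lowest control group of the species, at -0.23 for the proteasome and -0.25 for ubiquitin conjugation against -0.02 to 0.15 and 0 to 0.19 in the others; the heated means were 0.28 and 0.07, so the heated level of ubiquitin conjugation lay among those of the other controls. Of the tissue markers, 4 of 24 ciliated epithelium, 1 of 14 digestive gland and 1 of 11 muscle sequences were higher and 1 of 5 mitochondrial sequences lower, with list adjusted p of 0.102, 0.226, 0.28 and 0.229. The heated mean of the ciliated epithelium list was -0.1, among the other control groups (-0.11 to 0.26), and its matched control was at -0.37. The other control groups were scanned largely on other days, so these levels and those of the protein-degradation lists can hold a shift between scan days. The mantle and shell markers had a mean of 0.45 (0.23 to 0.8) on the heated arrays against -0.14 (-0.4 to 0.13) on the controls, with none of 3 called and a list adjusted p of 0.508.

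In all 265 sequences passed at 32 °C in M. trossulus, 149 higher and 116 lower. This count leaves out the control and the heated replicate 4, whose scanner files match each other's column in the authors' table; with both arrays as labelled 30 sequences passed, and with their labels exchanged 437. Among the other arrays, it was 158 without control replicate 5, 172 without control replicate 3, 168 without heated replicate 1 and 172 without heated replicate 6. It was 391 with scan day as a block, 312 with the replicate number as a block, 414 with array weights, 413 in the authors' value table and 131 with median centring. The balance moved as well, to 103 higher and 28 lower with median centring and to 141 and 70 with Agilent's own log ratios. Of the sequences called without 1 of 4 scan days, 65.9 to 100% had the same direction on it (relabelled 50%); the lowest share was among 372 called sequences.

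**Figure D2:**
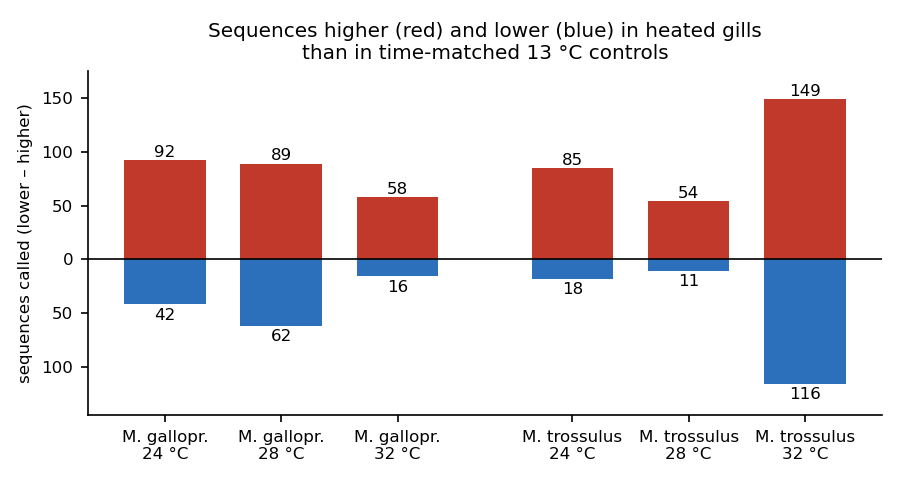
Bars give the number of sequences (y axis) higher (red, upward) and lower (blue, downward) in heated gills than in the 13 °C controls sampled at the same point of the ramp, by species and temperature. M. trossulus at 32 °C had 149 higher and 116 lower, and M. galloprovincialis 58 and 16.

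A common set of sequences was called in all of these comparisons. It comprised 19 sequences higher in all 6 and none lower in all 6. The described ones included 5 HSP70 sequences (MYC02822, MYC12419, MYC05570, MYC08447 and MYC11933), Dnajb4, the small 22kd heat shock protein, chaperonin MYC00474, CCAAT/enhancer binding protein and the immediate early response 5-like sequence. HSP70 MYC05570 was higher by 3.96 to 6.18 in the 6 comparisons. The species shared 41 higher and 5 lower sequences at 24 °C, 37 and 5 at 28 °C and 39 and 7 at 32 °C, where independent lists of those sizes would share 1.52 and 0.147, 0.932 and 0.132, and 1.68 and 0.36. Across sequences, which are not independent replicates, the log2 changes of the species had Pearson correlations of 0.59, 0.6 and 0.6 at the 3 temperatures.

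**Figure D3:**
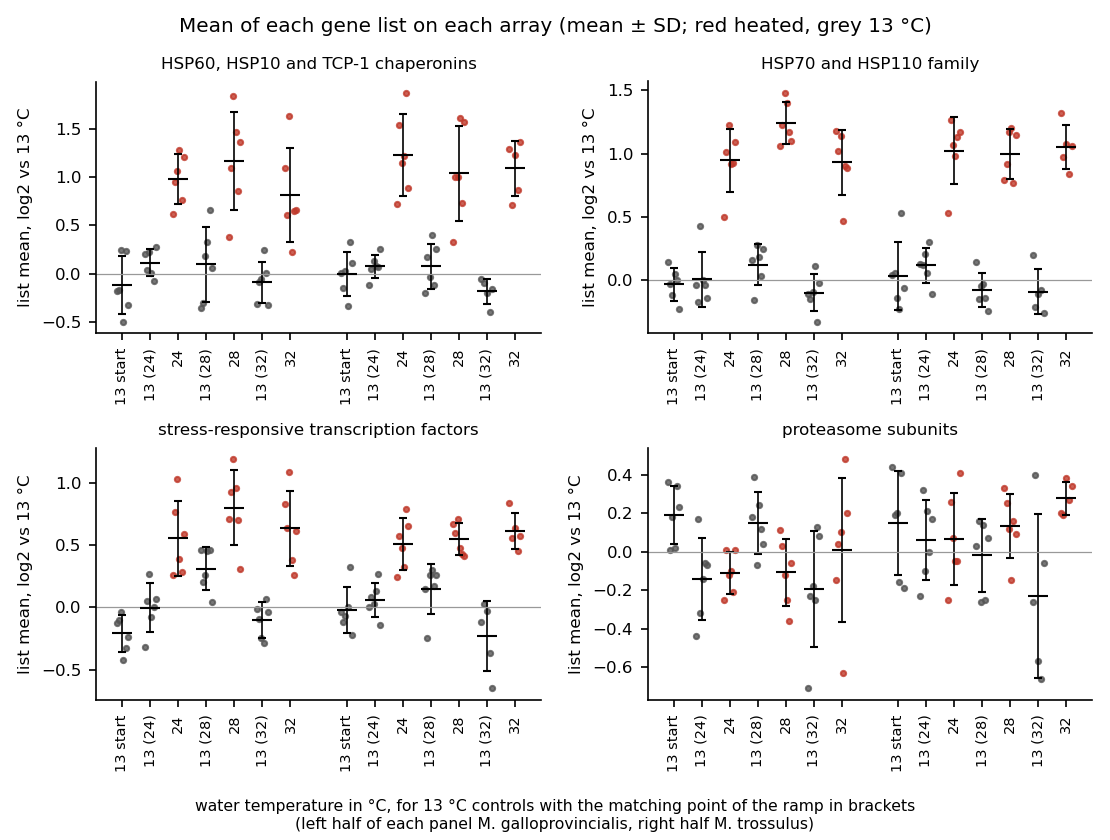
Each panel plots the mean log2 value of a gene list on every array against the mean of the 13 °C arrays of the same species (points, red heated and grey 13 °C), with the group mean and SD (bars); M. galloprovincialis is on the left. The chaperonin means of heated groups lay between 0.81 and 1.23 and those of control groups between -0.18 and 0.11.

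The second question was where the species differed in their response, and a test of the interaction found few such sequences. The one with the smallest p was the small heat shock protein MYC06670: against all 13 °C controls it was higher by 6.8 ± 0.47, 8.26 ± 0.5 and 7.54 ± 0.5 at 24, 28 and 32 °C in M. galloprovincialis and by 0.54 ± 0.47, 0.76 ± 0.47 and 0.63 ± 0.5 in M. trossulus (interaction adjusted p = 1.87e-18). Its 28 °C value in M. galloprovincialis is a lower bound, since 3 of those arrays were saturated. This sequence was read by a probe made from M. galloprovincialis, and the reference signal on it was 14.27 ± 0.51 (log2, SD) in M. galloprovincialis and 7.66 ± 0.43 in M. trossulus. On the M. californianus probe of the same sequence, too dim to pass the filter, the species difference did not pass (-0.79 ± 0.69, -1.03 ± 0.69 and -1.4 ± 0.73, adjusted p of 0.716 or more among all probes). The S-crystallin-like sequence (MYC04073), of a family related to glutathione S-transferases, rose in M. trossulus by 1.48 ± 0.29, 0.91 ± 0.29 and 2.7 ± 0.31 and was at 0.06 ± 0.29, 0.12 ± 0.29 and 0 ± 0.29 in M. galloprovincialis (0.00011). Glycine transporter 2 (MYC03523) was at 0.91 ± 0.16, 1.54 ± 0.16 and 1.15 ± 0.16 in M. galloprovincialis and at -0.08 ± 0.16, 0.37 ± 0.16 and 0.31 ± 0.17 in M. trossulus (0.000125), and the phosphatase PHOSPHO2 (MYC10173) at 1.34 ± 0.17, 1 ± 0.17 and 0.99 ± 0.17 against values from -0.05 to 0.18 (0.000125).

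The other sequences with an interaction that fall under the rule for named genes were sulfotransferase 1C2 (MYC09059), higher in M. trossulus by 1.29 to 1.49 and between -0.44 and -0.08 in M. galloprovincialis, the scavenger receptor MYC01328, higher by 1.99 to 3.53 in M. galloprovincialis and by 0.67 to 1.53 in M. trossulus, and toll-like receptor 2 (MYC06213), lower by -1.36 to -0.89 in M. galloprovincialis and between -0.23 and -0.06 in M. trossulus. Transformer-2a (0.0166), zinc finger protein 43 (MYC02081, 0.027), mitofilin (MYC01649, 0.0738), the tumor necrosis factor receptor MYC02394 (0.0898) and the inhibitor of apoptosis MYC02082 (0.109) did not pass. In all 17 sequences had an interaction, 7 of them with a description that the rule counts as informative and 2 on M. galloprovincialis probes. The beta-1,3-glucuronyltransferase 3-like MYC01987 (1.01e-08), whose description opens with a clone name and so falls outside that rule, and the undescribed MYC06003 (7.54e-11) were among the others. The count was 23 with scan day as a block, 17 with the replicate number as a block, 9 without the start controls, 9 with Agilent's own log ratios and 3 with the strict filter. It was 200 in the authors' table.

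The same difference was tested at each temperature against the matched controls, as M. trossulus minus M. galloprovincialis. At 24 °C 4 sequences passed: the small heat shock protein MYC06670 (-7 ± 0.82, adjusted p = 8.71e-09), toll-like receptor 2 MYC06213 (1.3 ± 0.25), a beta-1,3-glucuronyltransferase 3-like sequence (MYC01987, -2.05 ± 0.36) and the undescribed MYC06003 (2.12 ± 0.39). At 28 °C the same small heat shock protein (-6.43 ± 0.84, with the M. galloprovincialis rise saturated), MYC01987 (-2.33 ± 0.36) and MYC06003 (2.46 ± 0.39) passed. At 32 °C the small heat shock protein (-7.17 ± 0.88) and the S-crystallin-like sequence (3.03 ± 0.53) passed. The differences of the small heat shock protein are not bounds, since its probe may have lost a rise in M. trossulus. MYC01987 and MYC06003 fall outside the rule for named genes and are given because these counts of 4, 3 and 2 are small. Unadjusted p under 0.05 was reached by 249, 348 and 444 sequences. The counts were 5, 4 and 3 with scan day as a block, and 4, 3 and 2 with the replicate number as a block. Several of these calls ended under other processing, each with its direction kept. The S-crystallin-like sequence was at 2.41 (adjusted p = 0.0835) with all 84 arrays as labelled, 2.62 (0.0127) with the 2 exchanged, 3.77 (0.0978) with Agilent's own log ratios and 3.48 (0.134) in the authors' table. Toll-like receptor 2 MYC06213 was at 1.21 (0.0322) with median centring, 0.83 (0.864) with Agilent's ratios and 0.81 (0.908) in the authors' table. With Agilent's ratios and in the authors' table MYC01987 (0.086 and 0.0571 at 24 °C, 0.0133 in both at 28 °C) and, at 28 °C, the small heat shock protein (-4.83 and -5.08, adjusted p = 0.108 and 0.0282) did not pass either. With the strict filter limma called 0 at each temperature, since these sequences no longer entered. The 24 °C count was 7 without heated M. trossulus replicate 6, and the 28 °C count was 6, 6 and 7 without M. galloprovincialis control replicate 6, heated replicate 1 and heated replicate 5. Proteasome subunits were the only list that differed, at 28 °C (median 0.51, 0 of 17 members called, camera adjusted p = 0.00862, adjusted p = 0.84 with an estimated correlation). Its heated and control means there were -0.11 and 0.15 in M. galloprovincialis and 0.13 and -0.02 in M. trossulus.

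How the response changed between 24 and 32 °C was tested within each species. In M. galloprovincialis 3 sequences passed: toll-like receptor 2 MYC06213 went from -1.57 at 24 °C to -0.16 at 32 °C (difference 1.41 ± 0.25, adjusted p = 0.00214), Gll0560 protein (MYC06907) from -1.14 to 0.84 and the undescribed MYC06208 from 1.42 to -0.79. For the receptor the heated mean was -1.05 at 24 °C and -0.58 at 32 °C, and the matched control mean was 0.52 and -0.41. Against all 13 °C controls the heated level was -1.36 and -0.89. In M. trossulus 16 passed, 11 upward and 5 downward. This balance turned with median centring, with 2 upward and 10 downward of 12, and was 19 and 19 with scan day as a block. The described ones included outer arm dynein light chain 4 (MYC06936), a part of the motor of cilia, from -0.53 to 1.47 (difference 2 ± 0.35, 0.000366), a tumor necrosis factor ligand superfamily member 10 (MYC02459) from -0.94 to 1.48, D-aminoacylase (MYC02246) from -0.91 to 1.6 and a thioredoxin domain protein (MYC00085) from 0.3 to 2.05. Here the matched control means at the 24 and 32 °C points were -0.23 and -1.03 for the dynein and -0.15 and -1.17 for the ligand. They were -0.2 and -1.63 for D-aminoacylase and -0.24 and -1.09 for the thioredoxin domain protein. Oncoprotein-induced transcript 3 (MYC11056) differed by 3.88 ± 0.89 and did not pass (0.012). The difference from the matched control rose from 24 to 32 °C in the M. trossulus lists of proteasome subunits (median 0.54), tubulin, dynein and cilia (0.27) and ciliated gill epithelium (0.63), at camera adjusted p = 0.00606, 0.00606 and 0.00629, each at adjusted p = 0.417 with an estimated correlation, and with median centring none passed. The heated means were 0.06 and 0.28 for the proteasome, -0.14 and -0.07 for tubulin, dynein and cilia and -0.09 and -0.1 for ciliated epithelium at 24 and 32 °C. The control means went from 0.06 to -0.23, 0.1 to -0.26 and 0.16 to -0.37. These points were scanned largely on different days, so here and above it cannot be told whether heated or control animals moved.

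These counts of 3 and 16 moved with single arrays. Without each array in turn the M. galloprovincialis count lay between 1 (without control 24 replicate 6) and 32 (without control 32 replicate 4), and the M. trossulus count between 6 (without control 24 replicate 2 or heated 24 replicate 1) and 76 (without heated 24 replicate 6). They were 12 and 38 with scan day as a block, 4 and 20 with the replicate number as a block, and 0 and 10 with Agilent's own log ratios. As labelled, with both replicate 4 arrays in, the M. trossulus count was 2. Unadjusted p under 0.05 was reached by 657 and 956 sequences.

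The controls themselves were compared over the ramp. In M. galloprovincialis, Myc (MYC04528), a transcription factor of growth, differed from the start by 0.76, 2.16 and 1.27 at the 24, 28 and 32 °C points (adjusted p = 1.1e-05), Ala-tRNA(Pro) hydrolase (MYC08763) by -0.57, 2.74 and 2.45, and a microtubule-associated protein (MYC04393) by -0.12, -0.69 and -0.8. Toll-like receptor 2 MYC06213, which was lower in heated animals at 24 °C, was at -0.18, -0.26 and -1.11 in the controls. In M. trossulus, solute carrier family 25 member 38 (MYC03413) was at 0.44, 1.73 and 0.61, a monocarboxylate carrier of family 16 (MYC04226) at 0.72, 1.12 and -0.22 and deoxyhypusine synthase at 0.09, 0.53 and -0.24. The solute carrier and deoxyhypusine synthase were both among the falls of heated M. trossulus at 28 °C, where the matched control was at its highest. In all 195 sequences passed in M. galloprovincialis and 81 in M. trossulus, with 23 in both where independent lists would share 3.06, and the largest difference was at the 28 °C point for 152 and 39 of them. All 12 start controls were scanned on 1 day that held no other array and were read with another software version. Their median share of spots well above background was 29.8 and 29.4% against 17.2 to 26.2% in the other groups. The later points were scanned largely on different days too, so scan day and time cannot be told apart here. With scan day as a random block 96 and 33 passed, with the replicate number as a block 256 and 108, and with Agilent's own log ratios 54 and 22. The count of 195 was 112 without control 28 replicate 5, and that of 81 was 46 without control 32 replicate 6 and 132 without control 24 replicate 1.

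The M. galloprovincialis probes had been added to test the effect of sequence mismatch, and 354 pairs of an M. galloprovincialis and an M. californianus probe of 1 sequence were measured. The median pair differed at 3 bases. Across pairs, the change at 32 °C had a Pearson correlation of 0.82 in M. galloprovincialis and 0.87 in M. trossulus, and of 0.94 and 0.97 in the 23 pairs of identical sequence. The absolute change was larger on the M. galloprovincialis probe by 0.03 (0.43 against 0.39) in M. galloprovincialis and by 0.06 (0.55 against 0.49) in M. trossulus (2-sided sign-flip permutation test, p = 0.0175 and 7e-05; pairs are not independent replicates). Without the filter on dim probes 531 pairs were read, with correlations of 0.68 and 0.8 and a difference of 0.1 in both species (p = 1e-05, the smallest these permutations can give).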

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

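The tests of the exchanged arrays, of the small heat shock protein, of scan day and of the splits were chosen only after the result was seen; those of spread and of response size at 32 °C were written before, but the rule that reads the latter was changed after its value was seen.

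The small heat shock protein MYC06670 stood out because its response differed between the species, by -7 at 24 °C, -6.43 at 28 °C and -7.17 at 32 °C (log2, M. trossulus minus M. galloprovincialis). At 28 °C it was saturated on 3 heated M. galloprovincialis arrays, so the rise there is a lower bound. The difference is not, since a rise in M. trossulus may have been lost on the probe. It rose by 7.01, 7.35 and 7.85 in M. galloprovincialis and was at 0, 0.91 and 0.68 in M. trossulus, on a probe made from M. galloprovincialis. The M. californianus probe of the same sequence, which differs at 11 bases, read at most 27.4% of that change in M. galloprovincialis itself, so a mismatched probe can lose most of a rise of this sequence, though this lies above the bound written for that explanation. On the heated M. trossulus arrays that probe was well above background on 3 of 17 and the M. galloprovincialis probe on 9 of 17. At 28 °C the highest heated M. trossulus values were 2.12 on the M. galloprovincialis and 2.58 on the M. californianus probe. The highest matched controls were at -0.63 and -1.28. The lowest heated values there, -2.79 and -3.44, lay below every matched control. At 24 °C the highest heated values lay below the highest controls. At 32 °C they were -0.19 and -1.53 against -0.79 and -1.98. Too few arrays carried signal on both probes to show that the transcript did not rise. A mismatch of the probe to the M. trossulus transcript and a missing rise in M. trossulus therefore cannot be told apart, and the species difference on the M. californianus probe did not pass (-0.79, -1.03 and -1.4).

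The control and heated arrays of M. trossulus at 32 °C, replicate 4, stood out because each resembled the other's group. The HSP70 list, against the controls, had a mean of 0.88 on the array labelled control and of -0.18 on the one labelled heated; both arrays lie outside the comparisons. Each scanner file correlated across probes at 0.994 or more with the other array's column of the authors' value table and at -0.259 or less with its own, while the other 82 arrays matched their own column. The low correlation argues against a heated animal without and a control with a heat-shock response, since an unusual animal would still match its own column. An exchange of the scanner files of the pair is consistent with these values, and the 2 sources do not show which of them carries the true labels beyond the chaperone levels, which go with the authors' table.

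More sequences were called at 32 °C in M. trossulus (265) than in M. galloprovincialis (74), though with all 84 arrays as labelled the counts were 30 and 61. With the variance taken from the compared groups alone, 82 were called in M. trossulus and 20 in M. galloprovincialis, and the median SD was 0.4 in both, which argues against wider spread in M. trossulus. With scan day as a block, 391 and 112 were called, which argues against a constant shift between scan days. The block cannot show whether the arrays of a single day carry the excess. Scan days were numbered in order. Without day 11, 42 were called in M. trossulus and 52 in M. galloprovincialis, with fewer arrays left. Without day 8, 9 or 10 the counts were 114, 372 and 122 against 33, 50 and 88. Over 275 sequences called at 24 or 28 °C, the mean change at 32 °C, signed by the direction there, was 0.76 in M. trossulus and 0.72 in M. galloprovincialis, a difference of 0.04 (exact p = 0.784 over 213444 regroupings). This lies under the bound of 0.1 written for no larger response, which as first written would have excluded a larger response. After the value was seen, the bound was required to be met by more than the spread; the SD is 0.13, so a larger response of M. trossulus stays open. The higher count itself is not a test of a species difference. Only 2 sequences passed that test at 32 °C. On simulated data it found 5, 19.1 and 80.6% of differences of 0.5, 1 and 2 log2, so smaller differences stay open.

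Other species differences in the heat response, each past the test of the difference itself, were those of the glucuronyltransferase-like MYC01987 (-2.05 at 24 °C and -2.33 at 28 °C), the undescribed MYC06003 (2.12 and 2.46), toll-like receptor 2 MYC06213 (1.3 at 24 °C) and the S-crystallin-like MYC04073 (3.03 at 32 °C). The last did not pass with all 84 arrays as labelled, with the 2 exchanged, with Agilent's own log ratios or in the authors' table, and toll-like receptor 2 did not with median centring. With Agilent's ratios and in the authors' table neither did toll-like receptor 2, MYC01987 nor, at 28 °C, MYC06670; MYC06003 is not in the authors' table. The interaction of species and temperature was called in 17 sequences, and a change of the response between 24 and 32 °C in 3 in M. galloprovincialis and 16 in M. trossulus. Among lists, proteasome subunits differed between species at 28 °C (median 0.51) and, in M. trossulus, between 24 and 32 °C (0.54), as did tubulin, dynein and cilia (0.27) and ciliated gill epithelium (0.63); none of these 4 passed with an estimated correlation. From 24 to 32 °C the heated means of these M. trossulus lists were 0.06 and 0.28, -0.14 and -0.07, and -0.09 and -0.1. Their control means went from 0.06 to -0.23, 0.1 to -0.26 and 0.16 to -0.37. The 24 and 32 °C points were scanned largely on different days, so it cannot be told whether heated or control animals moved. No explanation of these changes was tested.

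In 70 tests of groups of arrays, 3 arrays lay far from the others of their group, where chance gives about 1 in 20: M. galloprovincialis control 24 replicate 3 in the HSP70 list (0.43), M. trossulus control 28 replicate 2 in the transcription factors (-0.25) and heated M. galloprovincialis 24 replicate 3 in its share of spots well above background (39.6%).

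Each count was compared with 100 splits of the same arrays, the real one included. As many sequences were called in 1 of 100 splits for the shared temperature effect (642, highest other 1), the interaction (17, highest other 1), M. galloprovincialis at 24 °C (134, highest other 24), 28 °C (151, highest other 82) and 32 °C (74, highest other 12), and M. trossulus at 24 °C (103, highest other 32), 28 °C (65, highest other 42) and 32 °C (265, highest other 132). The same held for the species difference at 24 °C (4, highest other 0), the change from 24 to 32 °C (3, highest other 1, in M. galloprovincialis; 16, highest other 2, in M. trossulus) and the controls over time (195, highest other 115; 81, highest other 6). For the species difference at 28 °C (3, highest other 3) and 32 °C (2, highest other 2), 2 of 100 splits gave as many. The share was under 0.05 for each count, by a rule written after the counts were seen and not adjusted over them. The species differences at 28 and 32 °C were equalled by another split, so chance is not excluded for them. For the other counts no other split drawn gave as many. The splits took no account of scan day, so for the controls over time they cannot tell time from scan day.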

How the results depend on the processing

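Scan day as a random block, the treatments of the exchanged arrays, leaving out each array and leaving out controls with raised chaperones were chosen after seeing the data. Counts below were within 1.5 times the value in the report unless listed. No background correction moved none of the 15 counts, and the replicate block and the mean of probes none. Between-array quantile scaling of the mean signal leaves ratios as they are by construction. The cause was not tested except where the construction of an alternative gives it.

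With Agilent's own log ratios the interaction was called in 9 sequences, the species difference at 24, 28 and 32 °C in 2, 1 and 1, the change from 24 to 32 °C in 0 (M. galloprovincialis) and 10 (M. trossulus), and the controls over time in 54 and 22. With median centring M. galloprovincialis had 294 at 28 °C and 47 at 32 °C, M. trossulus 131 at 32 °C, the change in M. galloprovincialis 0, and the controls over time 129 and 21. The balance of higher and lower turned with it, to 407 and 292 for the shared effect, 58 and 236 for M. galloprovincialis at 28 °C and 2 and 10 for the M. trossulus change. Centring moved the median change of all sequences by -0.2 at 28 °C in M. galloprovincialis and by 0.16 in the species difference there, and Agilent's ratios moved it by -0.11 at 32 °C in M. trossulus and by -0.12 in its change. In the authors' value table the shared effect was called in 1970, the interaction in 200, M. trossulus at 32 °C in 413, the species differences in 1, 0 and 1, and the changes in 0 and 73. That table differs in its normalization, its centring of controls by time point, its 4488 sequences and its arrays at once, so the cause of a move is not isolated; the centring leaves no test of controls over time.

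Without the filter on dim probes the M. trossulus controls over time had 134, 50 pairs of list and comparison passed and the probe pairs of M. galloprovincialis correlated at 0.68. The strict filter tests fewer sequences: the interaction had 3, M. galloprovincialis at 28 °C 77, M. trossulus at 28 °C 34, the species differences 0, 0 and 0, the M. galloprovincialis change 1 and the controls 97 and 47. With every probe, which counts a sequence more than once, the shared effect had 1336, the interaction 34, M. galloprovincialis 239, 322 and 164 at 24, 28 and 32 °C, M. trossulus 179, 142 and 569, the species difference at 28 °C 5, the M. trossulus change 30 and the controls 409 and 141. With M. californianus probes alone the species difference at 32 °C had 1, as the M. californianus probe of the small heat shock protein was too dim to be kept.

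With scan day as a fixed block M. galloprovincialis at 32 °C had 112 and the changes 12 and 38; this block cannot be estimated for the controls over time. With scan day as a random block the changes had 13 and 29 and the controls 96 and 33. With array weights M. galloprovincialis at 24 °C had 210, M. trossulus 246 at 24 °C and 414 at 32 °C, the species differences 9 and 5 at 24 and 28 °C, the changes 23 and 201 and the controls 299 and 136. At a threshold of 0.05, looser by construction, the shared effect had 1210, the interaction 28, M. galloprovincialis 264, 319 and 166, M. trossulus 165, 114 and 575, the species differences 7 and 8 at 24 and 28 °C, the changes 22 and 107 and the controls 614 and 321. Without the start controls the interaction had 9, and with the time-matched controls alone 9. Against pooled controls of a species, which are more arrays, M. galloprovincialis had 226, 280 and 152 and M. trossulus 193 and 119 at 24 and 28 °C. With an estimated correlation 13 pairs of list and comparison passed.

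As labelled, with all 84 arrays, M. trossulus at 32 °C had 30, the species difference there 1 and the M. trossulus change 2; exchanged, they had 437, 1 and 41, and the M. trossulus controls over time 141. Without the controls with raised chaperones the M. galloprovincialis change had 13.

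Of the named genes, 7 values reversed, none of which had passed in the report: in the authors' table MYC01095 (-0.27), MYC00486 (0.85), MYC03485 (-1.09), MYC12108 (-0.29), MYC03341 (-0.03) and MYC09846 (-0.08), and with Agilent's log ratios MYC03341 (-0.04). Of the 642 shared sequences, 0 changed sign at their largest change without background correction, with median centring or with Agilent's log ratios; at 32 °C 4, 9 and 11 did.

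Without each array in turn the shared effect ranged from 589 to 704, the interaction from 14 to 23, M. galloprovincialis at 28 °C from 108 to 166, and M. trossulus from 73 to 130, 44 to 77 and 158 to 380 at 24, 28 and 32 °C. M. galloprovincialis at 24 °C stayed within 1.5 times; at 32 °C it had 46 without heated replicate 3 and otherwise stayed within 1.5 times, upward too. The species differences ranged from 3 to 7, 3 to 7 and 2 to 3, the changes from 1 to 32 and 6 to 76, and the controls from 112 to 267 and 46 to 132. M. trossulus at 32 °C moved by over 1.5 times without control replicates 3 (172) and 5 (158) and heated replicates 1 (168) and 6 (172). The changes moved by over 1.5 times without M. galloprovincialis control 24 replicates 4 (7) and 6 (1), heated 24 replicate 6 (5), control 32 replicate 4 (32) and heated 32 replicates 1 (5) and 3 (7). In M. trossulus they did without control 24 replicates 1 (58), 2 (6), 3 (8), 4 (8) and 6 (7), heated 24 replicates 1 (6), 3 (8), 4 (8) and 6 (76), control 32 replicates 1 (7), 2 (67), 3 (9) and 6 (10), and heated 32 replicates 2 (36), 3 (10), 5 (9) and 6 (7).

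Signal limits these values: on the median array 22.6% of spots were well above background in the sample channel, so dim transcripts went unread and compressed changes cannot be excluded.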

Other observations

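Both tests of probe pairs were planned, and leaving out controls with raised chaperones, together or 1 at a time, was chosen after seeing the data.

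The ubiquitin-conjugation list held opposite members. Ubiquitin fusion degradation 1-like protein (MYC09067) was higher at 32 °C over both species by 0.44 ± 0.12 and a ubiquitin isopeptidase T (MYC05436) at 24 °C by 0.62 ± 0.15, and the ubiquitin-conjugating enzyme morgue (MYC03220) fell to -0.52 ± 0.11 at 24 °C. Among structural proteins, filamin (MYC13306) was higher at 32 °C (0.39 ± 0.1), kaptin (MYC03036) lower at 24 °C (-0.78 ± 0.14), cytoplasmic dynein light chain 2 (MYC06865) higher (0.84 ± 0.24 at 32 °C) and outer dense fiber protein 3 (MYC12008) lower (-0.64 ± 0.19). The GTPase RhoJ (MYC01446) rose by 1.59 ± 0.29, the cyclin-dependent kinase inhibitor p16Xic3 (MYC08301) by 0.97 ± 0.19 and proliferating cell nuclear antigen (MYC07419) by 0.49 ± 0.17 at 32 °C. Cytochrome c oxidase subunit 1 (MYC05648), encoded in the mitochondrion, was at -2.25 ± 0.44 in M. trossulus at 32 °C and at 0.13 ± 0.4 in M. galloprovincialis, and its interaction did not pass (adjusted p = 0.117). In the hemocyte list, myticin-A (MYC03485) was at 1.66 ± 0.74 in M. galloprovincialis and -0.6 ± 0.74 in M. trossulus at 24 °C and passed no test of the 2-way model.

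In the probe pairs of both species, the change at 32 °C had the same sign on both probes in 283 of 354 pairs in M. galloprovincialis and 296 in M. trossulus, and was larger on the M. galloprovincialis probe in 195 and 210. Pairs that differed in sequence, 331 of them and by at most 12 bases, had correlations of 0.81 and 0.87. Of the called sequences with several probes, all probes had the same direction in 102 of 104 for M. galloprovincialis at 24 °C and in 172 of 183 for M. trossulus at 32 °C.

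HSP70 MYC02822 was raised in several controls: it was at -2.7 in M. trossulus start control replicate 5, at -4.61 in M. trossulus control 32 replicate 5 and at -4.94 in M. galloprovincialis control 24 replicate 3, where the other arrays of these groups lay between -7.42 and -7.07, -7.23 and -6.44, and -7.88 and -7.29. Over the 19 sequences higher in all 6 heat comparisons, the second of these arrays was at -0.27 against the controls, and the others at 1.18 and 0.45. MYC02822 rose less in M. trossulus control 24 replicate 5 (-5.48, and 0.93 over the 19 sequences) and M. galloprovincialis control 28 replicates 6 (-5.43 and 0.62) and 4 (-5.74 and 0.48). Over the 19 sequences, though, these 3 arrays lay above M. galloprovincialis control 24 replicate 3 (0.45). These 3 and the second array were left out only 1 at a time, and without the second M. trossulus at 32 °C had 158 in place of 265. Without both M. trossulus start control replicate 5 and M. galloprovincialis control 24 replicate 3, the shared effect was called in 642 sequences and the M. galloprovincialis comparison at 24 °C in 118.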
